A study of Mus musculus with 99 samples.

How the data were processed

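RNA with a polyadenylated tail was captured from mouse embryos and amplified by the Smart-seq2 protocol, per the labels' protocols, and sequenced on an Illumina NovaSeq, per the series design. The submitters' processing notes name STAR, StringTie and DESeq2 and the genome build mm9, without versions or roles. Each of the 99 libraries came with 1 table of gene abundances. The authors deposited FPKM per gene (fragments per kilobase of transcript, scaled by the mapped fragments of the library), TPM scaled to 1000000 per library, and coverage (mean read depth over the gene), per the file headers. FPKM was used for every test. The deposited TPM were read only for their sum, and the deposited coverage served to compare depth: its ratio to FPKM was constant within 1 percent for 87.2 to 89.8 percent of genes of a library and ranged from 0.291 to 5.48 between libraries. Without counts no interval or detection floor was computed, and a value of 0 is described as listed at 0. Gapdh was at 0 in 34 and Polr2a in 44 of the 99 libraries, so a 0 can be a failed estimate. Some genes with such values are given as ranges over libraries, and others by their fold change alone.

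Rows with no gene name, 0.248 to 2.35 percent of the FPKM of a library, were left out, and values of a gene listed at several loci were summed, leaving 22619 genes. Libraries were grouped by the titles, genotypes and stages of the labels. Coordinates are those of the files. Correlations between libraries of a group, across genes on the log2(FPKM + 1) scale, ranged from 0.551 to 0.966, with medians of 0.636 in Ctrl and 0.707 in OE late 4-cell libraries.

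Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), with the libraries of the compared groups only and no covariate. Genes with an FPKM of at least 1 in at least as many libraries as the smaller group holds were tested, and calls have a Benjamini-Hochberg adjusted p below 0.05. All adjusted p-values of single genes come from this test. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Differences between stages in the effect of a genotype were tested as interaction contrasts. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Besides the lists given in the report, these were pluripotency and first lineages, glycolysis, heat shock, p53 response, G2/M genes, chromatin regulators, cumulus and granulosa markers and sperm markers. Sets of up to 300 genes that rise or fall with stage were taken from control libraries that the tested comparison does not use. These sets were tested with camera in the same way, but adjusted apart from the fixed lists. Dux, the level of 4 lists and the number of detected genes were compared by two-sided permutation tests in SciPy 1.17.1, exact where a group had fewer than 10 libraries and with 100000 resamples otherwise, adjusted over 42 tests. Overlaps were tested with Fisher's exact test.

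Named genes are a subset of Dux, the 10 largest rises and 10 largest falls past the threshold per genotype comparison, up to 4 members per list with the smallest adjusted p, and 5 rises and 5 falls with up to 2 members per list for stage comparisons, and 5 each way for interactions. The fixed lists, the main tests, this rule and most alternatives were chosen before the data were examined. Tests and families chosen later are named as such where they appear.

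The fit was tested on simulated data with the real genes' means and spreads, independent normal noise and 200 changed genes. The changed genes were drawn only from those with higher mean values, so the shares recovered do not hold for genes with low values. Of genes changed by 1 on the log2 scale, 1.49, 32.8, 0 and 11.9 percent were recovered in the KO zygote, early, mid and late 2-cell comparisons and 59.7, 19.4 and 16.4 percent in the OE zygote, early and late 4-cell comparisons. Of genes changed by 4, the shares were 66.7, 98.5, 75.8, 98.5, 100, 95.5 and 87.9 percent. Of genes changed by 2 on the log2 scale, 19.4 percent were recovered in the KO zygote and mid 2-cell comparisons (6197 and 6849 genes), 74.6 percent in the early and late 2-cell comparisons (8824 and 9630 genes), and 86.6, 70.2 and 44.8 percent in the OE zygote, early 4-cell and late 4-cell comparisons (9145, 6276 and 3261 genes). False calls made up 11.3 percent of calls in the mid 2-cell simulation. Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, FPKM rescaled to an equal sum per library, median-ratio scaling, a fit of all groups of the experiment, robust moderation, array weights, the replicate number as a block, and each library left out. Values under 1 FPKM set to 0, and the late and early 4-cell comparisons without libraries under 2500 and 5000 detected genes, were added after the data were seen.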

Results

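Gene expression was measured by Smart-seq2, a full-length RNA-seq method for very small samples, in 99 libraries from preimplantation mouse embryos. Dux encodes a transcription factor active around the onset of embryonic transcription, and the libraries ask what its loss and its excess do to the embryonic transcriptome. One set, in strain C57BL/6, held wild type (WT) and Dux knockout (KO) libraries, with 3 and 3 at the zygote stage, 6 and 4 at the early 2-cell stage, 4 and 4 at the mid 2-cell stage and 5 and 5 at the late 2-cell stage. The other set, in a strain labelled B6F2D1, held control (Ctrl) and Dux overexpression (OE) libraries, with 8 and 8 at the zygote stage, 10 and 10 at the early 4-cell stage and 16 and 13 at the late 4-cell stage. The labels do not say whether a library came from a whole embryo or a single blastomere, or from which mating, so p-values measure the spread between these libraries. The values are FPKM per gene from the deposited tables, which hold no read counts, and the total depth is therefore unknown. The ratio of coverage to FPKM, which scales with depth, ranged from 0.291 to 5.48 between libraries. Late 4-cell libraries held fewer detected genes (FPKM of at least 1) than earlier ones, with 3493 ± 1397 (SD, n = 16) in Ctrl and 3424 ± 1156 (SD, n = 13) in OE.

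Dux itself, at 57693399 to 57695423 on chromosome 10 (mm9), was read first as a check of the labels. At the early 2-cell stage it lay between 0.151 and 1.91 FPKM in the 6 WT libraries and was listed at 0 in 3 of the 4 KO libraries, with 0.0226 FPKM in the fourth (exact two-sided permutation test, p = 0.00952, adjusted p = 0.0667 over 42 tests). At the early 4-cell stage Dux was above 0 in 10 of 10 OE libraries, from 0.0429 to 0.626 FPKM, and listed at 0 in 10 of 10 Ctrl libraries (permutation test, adjusted p = 0.00042, from the smallest p that the resamples can give). At the other stages Dux gave no such check. The library labelled KO zygote replicate 1 had 1.95 FPKM of Dux, while the 3 WT zygote libraries had at most 0.00315 FPKM. Dux was above 0 in 3 of the 4 libraries labelled KO mid 2-cell, from 0.161 to 0.371 FPKM, and in 3 of the 5 labelled KO late 2-cell, up to 0.347 FPKM, with WT values of at most 0.0242 FPKM. Which part of the locus was deleted is not given in the sources used here, so Dux leaves directions at those 3 stages resting on the labels. Dux goes against the label, lying above every WT library of the stage, in KO zygote replicates 1 and 2 (1.95 and 0.00834 FPKM), in KO mid 2-cell replicates 1, 3 and 4 and in KO late 2-cell replicates 2, 3 and 5. In OE zygotes Dux did not differ detectably from Ctrl zygotes (exact permutation test, p = 0.903, n = 8 and 8). Gm4981, which lies 2172 bases from Dux and was singled out after its values were seen, was at 7.27 to 30.4 FPKM in the WT zygotes and at most 0.376 FPKM in the 3 KO zygotes. At the zygote stage this gene thus goes with the labels, also in KO replicate 1, at 0.274 FPKM. It was at 12.4 to 16.7 FPKM in WT early 2-cell libraries and listed at 0 in the 4 KO libraries of that stage. At the mid 2-cell stage it was above 0 in 3 of 4 KO libraries, up to 0.304 FPKM, and in 2 of 4 WT libraries, up to 1.71 FPKM, with medians of 0.0606 and 0.00116 FPKM. At the late 2-cell stage it was above 0 in 2 of 5 KO libraries, up to 0.171 FPKM, and in 4 of 5 WT libraries, up to 2.87 FPKM.

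**Figure D1:**
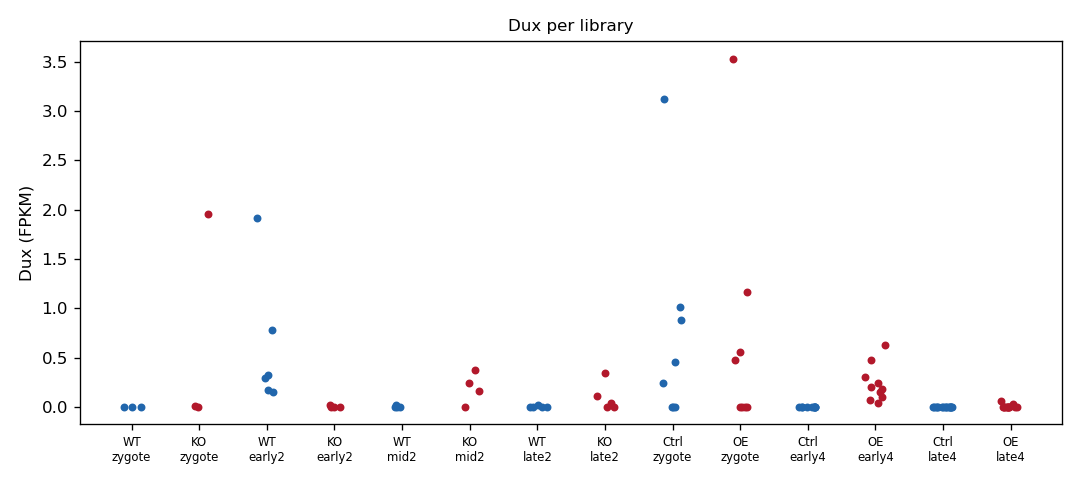
Dux in FPKM (vertical axis) in each library (points) of the 14 groups, with WT and Ctrl in blue and KO and OE in red. At the early 4-cell stage 10 of 10 OE libraries lie above 0, and the library labelled KO zygote replicate 1 stands at 1.95 FPKM.

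In zygotes, no gene passed the test between libraries labelled KO and WT. With limma on log2(FPKM + 1), 0 of 6197 genes had an adjusted p below 0.05 and 662 had an unadjusted p below 0.05. Fitting all WT and KO groups together gave 322 calls, and leaving out WT replicates 1, 2 and 3 in turn gave 1, 2 and 1. The list of maternal and oocyte transcripts stood at a mean log2(FPKM + 1) of 6.80 ± 0.375 (SD, n = 3) in KO and 5.87 ± 0.278 (SD, n = 3) in WT, an exact two-sided permutation p of 0.1, which is the smallest that 3 against 3 libraries allow. KO zygotes also held more detected genes, 6734 ± 1020 against 5111 ± 259 (SD, n = 3 and 3), and their ratio of coverage to FPKM was 2.52 ± 0.816 against 4.96 ± 0.501.

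At the early 2-cell stage, 8 of 28 measured 2-cell transcripts were called lower in KO libraries, while the list as a whole did not pass with an estimated correlation. Among the 8 was Gm4981, the gene near Dux, which also counts in the tests of this list. The deleted part of the locus is not given, so loss of Gm4981 with the deletion and a response to Dux cannot be told apart. Its fall is therefore no evidence of a response of 2-cell transcripts. The Zscan4 genes, 2-cell-specific zinc finger genes in 1 cluster on chromosome 7, fell: Zscan4d by 3.44 (SE 0.47, adjusted p = 0.0061) on the log2(FPKM + 1) scale, from 16.3 to 33.2 FPKM in the WT libraries to at most 3.41 FPKM in KO. Zscan4c fell by 3.20 (SE 0.47, adjusted p = 0.009), and Zscan4f was listed at 0 in all 4 KO libraries against 2.01 to 25.9 FPKM in WT. Outside the family, Tceal8 fell by 5.70 (SE 0.63), from 48.4 to 225 FPKM in WT to at most 7.05 FPKM in KO. Hmgn3, a nucleosome-binding protein, fell by 5.44 (SE 0.52), and Arid5b fell by 4.48 (SE 0.76). Gsto2 was at 6.84 to 23.1 FPKM in WT and listed at 0 in the 4 KO libraries.

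None of the 2-cell transcripts rose at this stage, and 21 fell when adjusted over the list alone. The list shifted down against other genes (camera, adjusted p = 2.43e-16), with an adjusted p = 0.086 with an estimated correlation. Its level per library was 1.14 ± 0.29 (SD, n = 4) in KO and 2.43 ± 0.316 (SD, n = 6) in WT, with 4 of 4 KO libraries below every WT library (exact permutation p = 0.00952, adjusted p = 0.0667). Other lists were lower in KO too, with maternal and oocyte transcripts at 6.79 ± 0.268 against 7.32 ± 0.221 (adjusted p = 0.114) and sperm markers at 0.486 ± 0.14 against 0.701 ± 0.0758 (adjusted p = 0.145). Zscan4 genes and Gm2016, which fell by 3.05 (SE 0.46), have near-identical copies, so the split of reads between copies is uncertain. Oog1, an oocyte transcript, was at 550 ± 43.5 FPKM (SD, n = 4) in KO and 1386 ± 345 FPKM (SD, n = 6) in WT. Prm2, a sperm protamine, was lower too, and KO libraries held 7520 ± 1033 detected genes against 8471 ± 280 in WT. In KO 5 genes rose, among them Cdo1, a cysteine dioxygenase, with 369 ± 89.8 FPKM (SD, n = 4) against 116 ± 32.9 (SD, n = 6), and Pdpk1, a kinase, with a log2 change of 1.91 (SE 0.32).

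In all, 36 of 8824 genes were called at the early 2-cell stage, 5 higher and 31 lower in KO. The count depended on single libraries: without KO replicate 4 it was 413, without KO replicate 3 it was 11 and without WT replicate 1 it was 87, and leaving out WT replicates 2, 3, 4, 5 and 6 and KO replicate 1 gave 18, 13, 18, 22, 19 and 20. Arid5b, Zscan4f, Gm2016, Oog1, Prm2 and Pdpk1 lost their call without at least 1 of the 10 libraries. Median-ratio scaling gave 58 calls and testing unfiltered genes gave 12.

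At the mid 2-cell stage, the calls between libraries labelled KO and WT included higher maternal transcripts and lower genes of ribosome production. Bcl2l10, an oocyte-enriched survival factor, was at 3877 ± 883 FPKM (SD, n = 4) in KO and 1053 ± 340 (SD, n = 4) in WT, and Bmp15, an oocyte growth factor, at 1002 ± 264.7 against 318.7 ± 122.7. Zar1, an oocyte RNA-binding protein, had a log2 change of 4.26 (SE 0.86). Rrn3, needed for RNA polymerase I initiation, fell by 2.61 (SE 0.48), and Nhp2, a small nucleolar ribonucleoprotein, fell by 2.87 (SE 0.61). The largest falls included Pdcd4, the PRAME-family gene Gm13078 and Rfpl4b, with log2 changes of -5.73 (SE 1.18), -5.17 (SE 0.83) and -5.15 (SE 0.96). Rln3 and Serpine2, a protease inhibitor, rose with log2 changes of 5.85 (SE 0.78) and 5.22 (SE 0.79).

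Of 41 measured maternal transcripts 6 rose and none fell (camera, adjusted p = 6.23e-08, and adjusted p = 0.181 with an estimated correlation). The level of cumulus and granulosa markers was higher in KO too, at 0.518 ± 0.443 (SD, n = 4) against 0.176 ± 0.118 (SD, n = 4), with an adjusted p = 0.281, and with a pseudocount of 0.1 all 4 KO libraries lay above every WT library (exact permutation p = 0.0286, adjusted p = 0.133). Ribosome biogenesis genes fell in 5 of 53 cases and ribosomal protein genes in 5 of 72, with camera adjusted p of 6.23e-08 and 9.34e-08, and adjusted p = 0.181 with an estimated correlation for both. Of 32 measured 2-cell transcripts 4 fell and 1, E330021D16Rik, rose (camera, adjusted p = 6.23e-08, adjusted p = 0.235 with an estimated correlation). Of 288 measured genes that normally rise from the zygote to the late 2-cell stage in WT, 64 fell and none rose, and of 262 that normally fall, 21 rose and 3 fell, with an adjusted p = 0.061 with an estimated correlation for both sets. KO libraries of this stage held 7357 ± 326 detected genes against 6250 ± 487 in WT, and 3 of them had 6555 to 7169 genes between 0 and 1 FPKM, against 2829 to 4102 in WT.

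The test called 317 of 6849 genes at the mid 2-cell stage, 144 higher and 173 lower. The count was 698 without KO replicate 1 and 72, 43 and 37 without KO replicates 2, 3 and 4, and it was 151, 65, 53 and 75 without WT replicates 1 to 4. Testing unfiltered genes gave 0 calls, array weights 692 and a fit of all groups 1550, and median-ratio scaling moved the split to 205 higher and 140 lower with a shift of 0.16 in the median of all genes. Of the genes named here, Bcl2l10, Gm13078, Rln3 and Serpine2 kept their call without each of the 8 libraries, Bmp15, Zar1, Rrn3, Nhp2, Pdcd4, Rfpl4b and E330021D16Rik lost it without 4, 6, 3, 7, 6, 4 and 7 of them in turn, and 35 of 46 genes named by the rule lost it without at least 1.

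At the late 2-cell stage, genes for making ribosomes and proteins were among those called lower in libraries labelled KO than in WT. Imp3, a processing factor of the small ribosomal subunit, was at 69.9 ± 21.1 FPKM (SD, n = 5) in KO and 542 ± 69.6 (SD, n = 5) in WT, a log2 change of -2.98 (SE 0.23). Rps9 fell by 2.16 (SE 0.31), the initiation factor gene Eif3a by 1.90 (SE 0.24) and the proteasome subunit gene Psmd7 by 1.79 (SE 0.22). Of 42 measured maternal transcripts 16 rose and 1 fell, with an adjusted p = 0.129 for the list with an estimated correlation and an adjusted p = 0.0667 for its level. Among those that rose were Tcl1, an oocyte-expressed kinase cofactor, at 9889 ± 2211 FPKM (SD, n = 5) against 2376 ± 509 (SD, n = 5), Bcl2l10 at 1592 ± 511 against 314 ± 114 and Gdf9, an oocyte growth factor, at 147 ± 31.9 against 46.8 ± 14.6. Dppa5a and Dppa2, expressed in pluripotent cells, fell by 2.53 (SE 0.43) and 1.34 (SE 0.24), while Id2 and Carm1 of the same list rose by 1.36 (SE 0.37) and 2.14 (SE 0.60), and the list did not pass (3 fell and 2 rose, of 23). Id2 and Carm1 lost their call without 3 and 6 of the 10 libraries in turn.

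Of 57 measured ribosome biogenesis genes 32 fell and none rose, and of 80 ribosomal protein genes 34 fell and 1 rose. Falls outnumbered rises in the proteasome (13 fell and none rose, of 33), translation initiation (15 and none, of 38), the spliceosome (10 and 1, of 42) and oxidative phosphorylation (14 and 1, of 66). Among 34 measured 2-cell transcripts 13 fell, including Trim43c by 1.97 (SE 0.26) and B020004J07Rik by 2.04 (SE 0.34). With the deposited scaling none of these fixed lists passed with an estimated correlation, where the adjusted p was 0.119 for ribosome biogenesis, 0.129 for ribosomal proteins, translation initiation, the spliceosome and maternal transcripts, 0.134 for the proteasome and 0.349 for 2-cell transcripts and oxidative phosphorylation. Sets from the WT stage course passed, but they were adjusted apart, as a smaller family than the fixed lists. Their adjusted p-values are therefore not comparable with those of the fixed lists. Of 300 genes that rise from the zygote to the mid 2-cell stage in WT, 208 fell and 4 rose (adjusted p = 0.01 with an estimated correlation). Of 271 that fall, 52 rose and 8 fell (adjusted p = 0.0135). These sets, and those used at the mid 2-cell stage, rest on the 3 WT zygote libraries, which held the fewest detected genes of the WT groups, so lower capture there can have shaped them.

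At this stage 1916 of 9630 genes were called, 1348 of them lower and 29.6 percent of the calls higher. A fit of all groups gave 903 calls. Median-ratio scaling shifted the median of all genes by 0.21 on the log2 scale and gave 840 higher and 844 lower, so the excess of lower genes is relative to the deposited scaling. With that scaling ribosome biogenesis genes fell in 23 of 57 cases and ribosomal protein genes in 23 of 80, with adjusted p of 0.0235 and 0.029 with an estimated correlation.

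**Figure D2:**
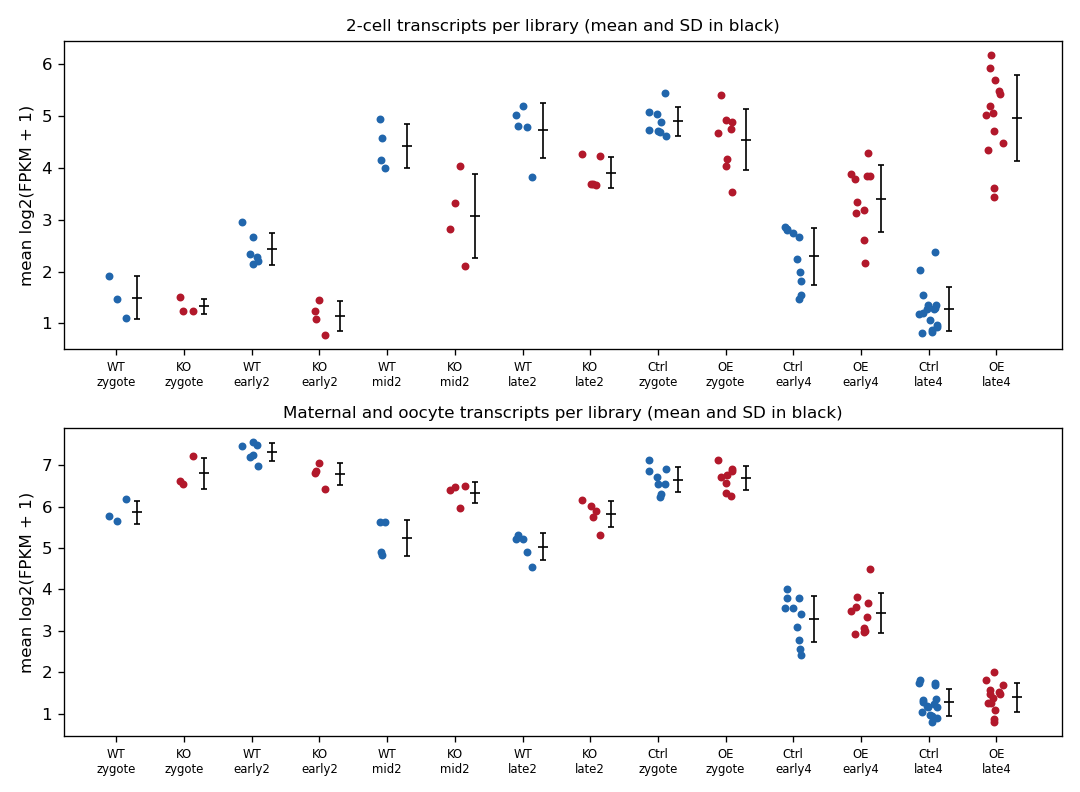
Mean log2(FPKM + 1) of 2-cell transcripts (top) and of maternal and oocyte transcripts (bottom) in each library (points), with the group mean and SD in black, WT and Ctrl in blue and KO and OE in red. All 13 OE late 4-cell libraries lie above the 16 Ctrl libraries for 2-cell transcripts, and the 5 KO late 2-cell libraries lie above the 5 WT libraries for maternal transcripts.

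The effect of the knockout was compared between stages. From the early to the mid 2-cell stage it differed in 556 of 10104 genes, higher at the mid stage in 379, among them Rln3 with a difference of 7.37 (SE 0.85), and lower in 177, among them Rnf149 with -4.83 (SE 0.75). From the mid to the late stage it differed in 57 of 11115 genes, among them Mrps34 with -7.16 (SE 1.21) and Rprd1b with 3.62 (SE 0.71). The count of 556 became 969 without KO mid 2-cell replicate 1, 324 and 354 without KO early 2-cell replicates 1 and 3, and 347, 351 and 347 without WT early 2-cell replicates 4, 5 and 6. The count of 57 became 180 and 88 without KO mid 2-cell replicates 1 and 2, 36, 27 and 27 without KO late 2-cell replicates 2, 4 and 5, and 20 and 29 without WT late 2-cell replicates 2 and 4.

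Zygotes labelled OE and Ctrl did not differ in any gene past the threshold. With limma 0 of 9145 genes were called and 1095 had an unadjusted p below 0.05, and fitting all groups of the experiment together gave 54, while leaving out Ctrl replicate 8 or OE replicates 2 or 4 gave 1 each. The 2-cell transcripts stood at 4.55 ± 0.593 (SD, n = 8) in OE and 4.91 ± 0.279 (SD, n = 8) in Ctrl zygotes, near the 4.73 ± 0.532 (SD, n = 5) of WT late 2-cell libraries and above the 1.5 ± 0.408 (SD, n = 3) of WT zygotes, which are of another strain and were not tested against them.

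At the early 4-cell stage, 6 genes were higher in OE than in Ctrl libraries and none was lower. They were Gm4301 and Gm4307, neighbours on chromosome 10, with log2 changes of 6.03 (SE 0.49) and 5.03 (SE 0.54), Gm11487 with 4.32 (SE 0.58), Zscan4f with 4.28 (SE 0.72), Zfp352, a zinc finger gene of the 2-cell list, with 3.80 (SE 0.61), and AU019990 with 2.78 (SE 0.54). Zscan4f ranged from 8.93 to 276 FPKM in OE and from 0 to 45.2 FPKM in Ctrl. The limma test covered 6276 genes, of which 349 had an unadjusted p below 0.05. Of 26 measured 2-cell transcripts 2 rose and 9 rose when adjusted over the list alone (camera, adjusted p = 1.18e-12, and adjusted p = 0.0237 with an estimated correlation). Fitting all groups together gave 27 calls, and 10 were made without OE replicate 3. AU019990 lost its call without each of 15 of the 20 libraries in turn.

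At the late 4-cell stage, 2-cell transcripts were higher in OE than in Ctrl libraries. Gm5662 ranged from 1404 to 5656 FPKM in the 13 OE libraries and from 0 to 22.7 FPKM in the 16 Ctrl libraries, a log2 change of 10.73 (SE 0.50). Gm2016, Gm8300 and Gm2022, close relatives of Gm5662 on chromosome 12, rose by 10.29 (SE 0.48), 9.75 (SE 0.45) and 8.03 (SE 0.56), and the assignment of reads among these copies is uncertain. Usp17lb, a deubiquitinase gene, rose by 8.42 (SE 0.50) and B020004J07Rik by 8.52 (SE 0.40). Of 22 measured 2-cell transcripts 17 rose and none fell, with a median log2 change of 6.40 (camera, adjusted p = 4.21e-38, and 4.95e-06 with an estimated correlation). The level of the whole list was 4.97 ± 0.834 (SD, n = 13) in OE and 1.27 ± 0.427 (SD, n = 16) in Ctrl, higher in 13 of 13 OE libraries than in every Ctrl library (permutation test, adjusted p = 0.00042).

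Outside that list, Dppa3, a maternal factor that protects DNA methylation, was at 27662 ± 13363 FPKM (SD, n = 13) in OE and 9634 ± 4950 (SD, n = 16) in Ctrl, and Cks2, a cell cycle kinase subunit, at 8956 ± 3265 against 1993 ± 1266. Hsf2, a heat shock transcription factor, fell by 3.50 (SE 0.34), from 1610 ± 987 to 147 ± 90.2 FPKM. The chromatin regulators Tet2, Kdm6a and Kdm6b fell by 2.69 (SE 0.52), 2.44 (SE 0.51) and 2.42 (SE 0.59), but of 33 measured chromatin regulators 6 fell and 1, Dppa3, rose, and the list did not pass (camera, adjusted p = 0.349). The largest falls were in Tmem55a, by 5.92 (SE 0.74), and Lsm3, an RNA-binding splicing factor, by 5.40 (SE 0.95). Tmem55a was listed at 0 in 8 of 13 OE libraries, with up to 55.2 FPKM in OE and 15 to 944 FPKM in Ctrl. Lsm3 was listed at 0 in 7 of 13 OE and 1 of 16 Ctrl libraries, with up to 90.7 and 1247 FPKM. A 0 can be a failed estimate, so the sizes of these falls are uncertain. Ribosomal protein genes rose in 6 of 63 cases and none fell (camera, adjusted p = 0.0211, and adjusted p = 0.756 with an estimated correlation). The test called 427 of 3261 genes, 246 higher and 181 lower, and 383 to 446 when single libraries were left out. Fitting all groups together gave 872, and the ratio of coverage to FPKM was 0.711 ± 0.311 in OE and 1.13 ± 0.404 in Ctrl. The effect of overexpression differed between the late and the early 4-cell stage in 146 of 7452 genes, with Gm8300 at 9.19 (SE 0.93) and Rap2b at -5.28 (SE 0.996), and array weights and a fit of all groups gave 250 and 265.

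Genes lower in KO were compared with genes higher in OE, in experiments that share no library. Of 12 genes lower at the early 2-cell stage that were also tested in late 4-cell libraries, 5 were higher in OE, where 0.82 would be shared by independent lists (two-sided Fisher's exact test, adjusted p = 0.00339 over 18 tests). They were Gm2016, Gm2022, Zscan4c, Zscan4d and Zscan4f, all members of 2 gene families. For genes lower at the mid 2-cell stage the overlap was 33 against 11.2 (adjusted p = 4.27e-08), and for the late 2-cell stage 116 against 73.1 (adjusted p = 4.27e-08). With genes higher in OE at the early 4-cell stage the 3 lists shared 1, 0 and 0 genes, and none passed. In the opposite direction, genes higher in KO at the late 2-cell stage and lower in OE at the late 4-cell stage numbered 12 against 6.56 (adjusted p = 0.0965). Genes moving the same way in both were fewer than expected there, with 29 lower in both against 53.3 (adjusted p = 0.000131) and 2 higher in both against 9.01 (adjusted p = 0.0271). The other 9 tests had adjusted p of at least 0.274. Genes are not independent replicates, and stages and strains differ between the experiments.

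The stage course in WT and Ctrl embryos gives the background. From the early to the mid 2-cell stage in WT, 1205 genes rose and 2787 fell of 8867, with Spry2, a growth factor signalling inhibitor, up by 9.07 (SE 0.44) and the homeobox gene Obox6 by 8.07 (SE 0.38), while Crabp2 fell by 6.32 (SE 0.86). From the mid to the late stage 1747 rose and 183 fell of 8993, with Cox17 and Sssca1 among the largest rises, at log2 changes of 5.96 (SE 1.02) and 6.46 (SE 0.45). That total of 1930 was 1208, 1195, 1085 and 1239 without WT late 2-cell replicates 2, 3, 4 and 5. The mean number of detected genes moved the same way, with 8471, 6250 and 9429 in WT early, mid and late 2-cell libraries. The direction of both splits therefore cannot be told apart from this shift in detection. From the zygote to the early 2-cell stage 2841 rose and 195 fell of 8924, but the same change in KO libraries, computed after the data were seen, gave 4 calls of 8045 genes, with 1076 at an unadjusted p below 0.05. Of the 2487 WT rises tested there, 1734 also went up in KO, with a median log2 change of 0.44. The median over the 2841 in WT was 1.84, but these genes were chosen by their rise in WT, which favours a larger value there. Array weights gave 902 calls in WT and a mean FPKM of at least 5 gave 1473. In Ctrl, 1847 genes rose and 3195 fell of 8568 between the zygote and early 4-cell stages, including the oocyte gene Tcl1b4, which fell by 8.15 (SE 0.70). All 8 libraries labelled Ctrl zygote correlated best with a WT 2-cell stage, though the WT zygote reference rests on 3 libraries with few detected genes. The Ctrl change from the zygote holds for that stage only if those labels are right. Between the early and late 4-cell stages 110 rose and 1508 fell of 5215, with the water channel gene Aqp3 up by 3.89 (SE 0.79) and the oocyte gene Btg4 down, from 21.7 to 270 FPKM to at most 77.2 FPKM. Median-ratio scaling shifted the median of all genes by -0.72 between Ctrl zygote and early 4-cell libraries. It changed that split to 1115 higher and 4553 lower. The mean number of detected genes also fell, with 9381, 6269 and 3493 in Ctrl zygote, early 4-cell and late 4-cell libraries. The excess of falls in both Ctrl changes therefore cannot be told apart from this shift in detection.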

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

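Tests of other splits of the libraries, of scaling, of depth and of the zygote share were chosen after the results were seen, and both tests on receptor genes before. Single libraries stood far from the others of their group in 8 of 59 sets of values examined, where chance gives about 1 in 20. For Dux these were Ctrl zygote replicate 6 at 3.12 FPKM, OE zygote replicate 7 at 3.53 FPKM, WT early 2-cell replicate 4 at 1.91 FPKM, KO early 2-cell replicate 3 at 0.0226 FPKM, WT late 2-cell replicate 3 at 0.0223 FPKM and WT mid 2-cell replicate 3 at 0.0242 FPKM. In the last 3 groups every other library held 0, where any value above 0 stands out. The rate of 1 in 20 therefore does not apply to them, and the number of such libraries is no test. That rate assumes normally distributed values. Dux was examined as FPKM, not on a log2 scale, and was above 0 in 5 of 8 Ctrl and 5 of 8 OE zygotes. The rate need not apply to the other Dux values either. The mean level of sperm markers was 1.66 in KO mid 2-cell replicate 3 and 0.982 in OE early 4-cell replicate 9. The effect of the knockout differed between the early and mid 2-cell stages in 556 genes and between the mid and late stages in 57, and that of overexpression between both 4-cell stages in 146.

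Whether other groupings of the libraries give as many calls was examined by counting calls in other splits. Of 100 splits the real one alone gave as many calls, a count of 1, for KO late 2-cell (1916 against 4 at most in the others), OE early 4-cell (6 against 3), OE late 4-cell (427 against 94), the WT changes from the early to the mid (3992 against 9) and from the mid to the late 2-cell stage (1930 against 13), Ctrl zygote to early 4-cell (5042 against 1706), Ctrl early to late 4-cell (1618 against 44), and the interactions with 556 (against 314) and 146 calls (against 11). The same held in 35 splits for KO mid 2-cell (317 against 5) and in 84 for the WT zygote to early 2-cell change (3036 against 8). The smallest share that can be reached is 0.01 with 100 splits and 0.0286 with the 35 of KO mid 2-cell. Chance is thus unlikely for these counts but not excluded. This holds only if the libraries are independent, which the labels do not say. For KO early 2-cell 2 of 100 splits gave at least 36, and the other one gave 533. It set KO replicates 1, 2 and 3 with WT replicate 1, which points to a structure of the samples in which KO replicate 4 and WT replicate 1 stand apart from their groups. The libraries set together held the fewest detected genes of the comparison, 6360 to 8074, against 8324 to 8873 in the others. They also had the lowest FPKM sums. Genotype and the number of detected genes are therefore partly entangled in the KO early 2-cell comparison. Leaving out WT replicate 1 alone gave 87 calls and leaving out KO replicate 4 alone 413. For the interaction with 57 calls 2 of 100 splits gave as many, with 100 in the other one. In OE zygotes all 100 splits gave at least the real count of 0, with up to 18. The 10 splits of the KO zygote comparison are too few for a share below 0.05, with a real value of 0 and up to 3 in the others.

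At the late 2-cell stage 70.3 percent of calls were lower in KO. With median-ratio scaling 50.1 percent were lower, but that scaling brings the median change of all genes close to 0 (0.03), which favours an even split by itself. The authors' scaling and library composition therefore cannot be told apart from other causes of the excess of lower calls. The tables argue against scaling as the whole cause for the set of normally rising genes: with median-ratio scaling, which moved the median change of the set from -1.17 to -0.917, 52.3 percent of its 300 genes were called lower, against 8.76 percent of all genes tested, a ratio of 5.97. A slower course in KO embryos stays open and was not tested.

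In KO mid 2-cell replicates 1, 3 and 4, 8086 to 8773 genes were listed at 0, against 12109 to 13240 in WT. Deeper sequencing is argued against by the highest coverage to FPKM ratio of the 3, which was 0.744 of the WT median. Olfactory and vomeronasal receptor genes were taken as silent in embryos. They were above 0 in at least 1.49 times the highest WT share, between the bounds of the test. Background reads therefore cannot be told apart from other causes. The receptor genes are also an imperfect measure of background, as not all were silent. Olfr1166 was at 4.28 to 12.2 FPKM in KO and 0 to 1.38 FPKM in WT early 2-cell libraries. In KO mid 2-cell replicates 1, 3 and 4, Dux lay at percentiles 99.2, 98.4 and 96.2 among the receptor genes (96.15 at the lowest). This leaves open for Dux too whether its reads could be background. A mislabelled library was not tested.

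The WT rise from the zygote to the early 2-cell stage may come in part from fewer transcripts captured in WT zygote libraries. Of the 2841 rising genes, 81.1 percent had a mean of at least 1 FPKM in KO zygotes and 42.7 percent in WT zygotes. The genes were chosen by their rise from the same WT zygote libraries, which favours a lower share there. The shares alone therefore cannot show lower capture. Detected genes, which were not chosen this way, averaged 6734 in KO and 5111 in WT zygotes. Genotype differs along with capture between KO and WT zygotes, so a biological difference stays open and was not tested.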

How the results depend on the processing

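The tests with values under 1 FPKM set to 0 and without libraries with few genes were chosen after the results were seen; they kept all counts they cover within 1.5 times, with 457 calls at the late and 4 at the early 4-cell stage. Robust moderation and FPKM rescaled to an equal sum did so for every count. Without a filter the calls were 12 at KO early 2-cell, 0 at KO mid 2-cell, 1157 for WT mid to late 2-cell and 367 for the KO early to mid interaction. A mean FPKM of at least 5, which tests fewer genes, gave 1473 (WT zygote to early 2-cell), 2654 (early to mid) and 1159 (mid to late). Median-ratio scaling gave 58 at KO early 2-cell, and a pseudocount of 0.1 gave 97 for the KO mid to late interaction. All groups in 1 fit gave 322 (KO zygote), 1550 (KO mid 2-cell), 903 (KO late 2-cell), 54 (OE zygote), 27 (OE early 4-cell), 872 (OE late 4-cell), 1878 (WT zygote to early 2-cell) and 871, 291 and 265 (the interactions). Array weights gave 692 (KO mid 2-cell), 902 (WT zygote to early 2-cell), 37 (KO mid to late interaction) and 250 (OE interaction). Apart from the filters, the cause was not tested. The median of all genes shifted by 0.25, -0.28 and 0.18 in the WT stage changes in order and by -0.16, -0.41 and -0.10 in the Ctrl stage changes and the OE interaction with FPKM rescaled to an equal sum, and by -0.21 (WT zygote to early 2-cell), -0.22 (mid to late) and -0.11 (Ctrl early to late 4-cell) with median-ratio scaling.

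With the replicate number as a block the calls were 3 (KO early 2-cell), 23 (KO mid 2-cell), 3 (OE early 4-cell), 1123, 2371 and 848 (WT stage changes in order), 853 (Ctrl early to late 4-cell) and 126 and 3 (KO interactions), and 1759 at KO late 2-cell, 365 at OE late 4-cell and 0 in both zygote comparisons. No comparison had every pair of the same number correlated over 0.1 or every library closest to its own number. Outside KO early 2-cell the numbers showed no clear pairing, with mean correlations from -0.0343 to 0.0356. At KO early 2-cell the pairs lay from 0.0588 to 0.15, with a mean of 0.0895. There 3 of 4 libraries correlated best with their own number, so a pairing in that comparison stays open.

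Leaving out single libraries gave 0 to 2 (KO zygote), 11 to 413 (KO early 2-cell, lowest without KO replicate 3 and highest without KO replicate 4), 37 to 698 (KO mid 2-cell, without KO replicates 4 and 1), 1335 to 2490 (KO late 2-cell), 0 to 1 (OE zygote), 5 to 10 (OE early 4-cell), 383 to 446 (OE late 4-cell), 2289 to 3135, 3415 to 4199 and 1085 to 1775 (WT stage changes in order), 4841 to 5111 and 1304 to 1747 (Ctrl stage changes), and 324 to 969, 20 to 180 and 114 to 153 (interactions). Of the named genes 10 of 17 at KO early 2-cell, 35 of 46 at mid 2-cell, 7 of 74 at late 2-cell, 1 of 6 at OE early 4-cell and 4 of 49 at OE late 4-cell lost a call without at least 1 library, and none changed sign.

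Between Ctrl zygote and early 4-cell libraries, 6 of the 4316 genes called both as deposited and with median-ratio scaling changed direction. Of the levels and lists, direction changed in these cases, none past the threshold. The sperm marker level at KO late 2-cell became -0.0217 with a pseudocount of 0.1. For gene lists the adjusted p after the change was 0.952 and 0.91 for G2/M genes at KO zygote with median-ratio scaling and FPKM rescaled to an equal sum, 0.992 for the p53 response, spliceosome and translation initiation at KO early 2-cell with that rescaling, 0.828 for spliceosome and translation initiation there with the block, 0.718 and 0.876 for G2/M and heat shock genes at KO late 2-cell and 0.926 for translation initiation at OE early 4-cell with median-ratio scaling, and 0.985 for heat shock at OE late 4-cell with the rescaling. Of 112 list tests 31 lost their call with an estimated correlation. The 112 include tests that were never called and so had no call to lose. Of 389 named results 96 lost it without a filter and 35 with all groups in 1 fit, and of 385 tested with the replicate number as a block 85 lost it. All 5 overlaps that passed, 3 above and 2 below the expected count, kept an adjusted p below 0.05 with a change of at least 1 and with median-ratio scaling, and genes higher in KO at the late 2-cell and lower in OE at the late 4-cell stage passed with a change of at least 1 (adjusted p = 0.00858). Total depth is unknown, which limits statements on low values.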

Other observations

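The test of the late 4-cell libraries without Dux and the gene families below were chosen after the results were seen. At the late 2-cell stage 18 of 50 histone cluster genes rose in KO and 2 fell (camera, adjusted p = 4.04e-06 over 53 tests, and adjusted p = 0.675 with an estimated correlation). Capture was of RNA with a polyadenylated tail, so any histone RNA without such a tail was not targeted. Of 26 Mediator genes 12 fell and 2 rose, and of 72 mitochondrial ribosomal genes 17 fell and none rose (adjusted p = 0.0358 for both, and 0.542 and 0.788 with an estimated correlation). Chaperonin Cct genes fell in 3 of 7 cases there (adjusted p = 0.0358, and 0.542 with an estimated correlation). With no gene called, histone cluster genes shifted down in OE zygotes (adjusted p = 0.0139, and 0.788 with an estimated correlation) and Mediator genes up in OE early 4-cell libraries (adjusted p = 0.0139, and 0.542 with an estimated correlation).

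Of the remaining lists, pluripotency and first lineage genes fell in 1 of 14 cases at KO mid 2-cell (camera, adjusted p = 0.0211, and adjusted p = 0.338 with an estimated correlation). At KO late 2-cell 2 of 23 rose and 3 fell, G2/M genes rose in 3 and fell in 5 of 32 cases, chromatin regulators rose in 1 and fell in 10 of 50, heat shock genes rose in 3 and fell in 4 of 20, and p53 response genes rose in 1 and fell in 3 of 21, and none of these 5 lists passed (camera, adjusted p of at least 0.371). Of 14 glycolysis genes 1 rose (adjusted p = 0.042, and adjusted p = 0.396 with an estimated correlation). Cumulus and granulosa markers had 1 of 2 measured members fall there, Amhr2, and of 4 sperm markers none was called. No list had a called member in either zygote comparison.

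Late 4-cell OE libraries held 2-cell transcripts while Dux was listed at 0 in 11 of 13. All 11 lay above every Ctrl library in the level of the list, the lowest at 3.44 and the highest Ctrl library at 2.38, but Gapdh or Polr2a was also at 0 in each of the 11, so a 0 there can be a failed estimate and whether Dux RNA was still present stays open.

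Libraries labelled Ctrl and OE zygote resembled 2-cell libraries of the other strain. By correlation across genes with the mean of each WT stage, 5 of 8 Ctrl zygotes were closest to the early and 3 to the mid 2-cell stage, and 7 of 8 OE zygotes to the early and 1 to the mid stage. Of the 3 KO zygotes 2 were closest to the early 2-cell stage and 1 to the zygote. The WT zygote mean rests on 3 libraries with 5111 detected genes on average, against 8471 in 6 WT early 2-cell libraries. This can lower the correlation of any library with the WT zygote, so the match alone does not decide the stage. Genes are not independent replicates, and the strains differ.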
